A study of Canis lupus familiaris with 12 samples.

How the data were processed

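RNA of the cerebral cortex of 12 female beagles was hybridized to canine Affymetrix expression arrays, 1 array per dog, in 4 groups of 3 dogs given by age (12 yr, old, or 1 yr, young) and diet (animal-protein based, APB, or plant-protein based, PPB). Per the labels, total RNA was extracted with Trizol and labelled with biotin by a 3' amplification method. The authors summarised the arrays with GCRMA, a method that corrects each probe for background by its GC content, normalizes the arrays and gives 1 value per probe set; its version is not given. The deposited values are on a log2 scale, which was checked on their range and floor. They were used as deposited, with no further normalization. GCRMA values carry no detection calls, and values near the background make folds uncertain and may understate them. For arrays, no depth in counts applies, and the number of arrays limits the precision.

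The table held 23913 probe sets. After 77 control probe sets were set aside, 23836 remained, and the 10835 with a log2 value of at least 4 on at least 3 of the 12 arrays were tested. Gene names came from the annotation table of the array, which paired 10549 probe sets with 1 symbol and 138 with several symbols, and left 13149 unnamed. Of the 10687 annotated probe sets, 10046 matched a gene identifier in a reference gene table of the assembly UU_Cfam_GSD_1.0, which was used for names and for which genes neighbour each other. No coordinates are given, since the files name no genome build. The tested probe sets with 1 symbol numbered 6276 and stood for 4527 genes, of which 1228 had more than 1 probe set. Where a gene is named, its values are those of its probe set with the highest mean over all arrays.

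Each probe set was fitted in limma 3.58.1 (R 4.3.3) with 1 mean per group over all 12 arrays and empirical Bayes moderation, with 8 residual and 3.01 prior degrees of freedom. The 7 contrasts, tested two-sided, were age averaged over diets, age within each diet, diet averaged over ages, diet within each age, and the age by diet interaction, which is the diet difference in old dogs minus that in young dogs. P-values were adjusted by the Benjamini-Hochberg method over the 10835 probe sets of each contrast, with a threshold of 0.05. Differences are log2, old minus young or PPB minus APB, with their moderated standard error (SE), and group levels are means with the standard deviation (SD) between dogs. Agreement of an effect between strata was measured as Pearson's r across probe sets, which are not independent replicates.

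Before the data were examined, 40 gene lists were fixed, 10 of cell type markers and 30 of pathways, complexes and functions, together with the groups, contrasts, tests, alternatives and the rule for named genes. On the 4527 genes with 1 probe set each, the 31 lists with at least 5 measured members were tested for age, diet and interaction with camera at a preset correlation of 0.01, adjusted over the 31 lists. Camera compares the members of a list with the other genes. The median difference over all 4527 genes was -0.06 for age and -0.05 for diet, so camera can point up for a list slightly below 0. The tests were repeated with camera at a correlation estimated for each list, and with fry, which asks whether the members of a list move one way and compares the list with no other genes. A further 9 lists had fewer than 5 measured members and were not tested: oligodendrocyte precursors (0 measured), choroid plexus and ependyma (2), blood (0), interferon response (3), glutamate receptors and postsynaptic density (2), GABA receptors and transport (4), cell cycle (4), circadian clock (4), and isoflavone and oestrogen-responsive genes (4).

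The rule for named genes took, for the averaged age and diet contrasts, the 10 genes with the largest rise and the 10 with the largest fall past the threshold and of the same sign in both strata, or the 10 with the smallest p where fewer passed. It also took the 5 genes with the smallest p for the interaction and for diet within each age, up to 4 members of each list with the smallest p, and the RNA quality controls. Members of lists named beyond that were chosen after their values were seen. RNA quality was followed by the log2 difference between the 3' and 5' control probe sets of actin and of GAPDH on each array, compared between ages and diets, with the array median and interquartile range, by 8 two-sided exact permutation tests over 924 splits.

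Alternatives fixed in advance were no intensity filter, a filter at log2 6, quantile normalization, centring each array on its median, a variance trend, robust moderation, no moderation, array weights, other thresholds, 1 probe set per gene, the mean of all probe sets of a gene, replicate numbers as blocks, fits on only the groups compared, and leaving out each dog in turn. Covariates for actin, GAPDH and globin-related probe sets, and median centring for the gene lists, were added after seeing the data. In other splits of the dogs, group labels were permuted and each count was taken again.

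The fit was tested on simulated data with 10835 probe sets and 12 arrays, of which 200 probe sets differed. For a log2 difference of 1, it recovered 80% of them for the averaged age contrast, 83% for the averaged diet contrast, 64.5% for age in APB-fed dogs, 61% for diet in old dogs and 25% for the interaction, all with the right sign. False calls beside them numbered 11, 6, 6, 9 and 4. For a difference of 0.5, the shares were 29%, 21.5%, 0%, 0% and 0%. For a difference of 2, they were 99%, 99.5%, 94%, 93.5% and 81%, with 16, 14, 15, 12 and 8 false calls. The simulated noise was independent between probe sets, with no variation shared across an array. These shares and false calls may therefore not carry over to the data, where 25.1% of probe sets passed for age. In simulated genes without correlated members, moving the 43 oxidative phosphorylation members down by 0.5 between the diets led to a call of that list and of no other, with the preset and with the estimated correlation. Median standard errors in the data were 0.139 for the averaged contrasts, 0.197 within a stratum and 0.278 for the interaction. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Scanner files were not used here.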

Results

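Gene expression was measured in the cerebral cortex of 12 female beagles on canine expression arrays, 1 array per dog, so each value comes from a separate animal. Old dogs (12 yr) and young dogs (1 yr) had eaten an animal-protein based diet (APB) or a plant-protein based diet (PPB) for 12 months, with 3 dogs in each of the 4 groups. At the start, old dogs were 11.1 yr and young dogs 8 weeks old, so the diets were eaten at different stages of life. Per the labels, APB held 28% protein, 23% fat and 5% fibre, and PPB held 26% protein, 11% fat and 15% fibre, so the diets differed in more than their protein source. The labels give APB 5.38 kcal per g and an intake of 166 g per day. They give PPB 4.75 kcal per g and 237 g per day, so the amount eaten differed as well. Young dogs ate freely and old dogs were fed to hold their weight, so age and feeding regimen cannot be told apart. The array files of old dogs are numbered 339 to 344 and those of young dogs 345 to 350, so array order cannot be told apart from age either. The files of the diets alternate in number. Array medians lay between 3.39 and 3.46 on the log2 scale, and 43.95 to 44.6% of the probe sets of an array reached the intensity minimum. The number of arrays limits the precision of every value.

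Over the tested probe sets, the first principal component held 40.3% of the variance and placed all old dogs on one side and all young dogs on the other. Pearson's r between arrays, across probe sets, ranged from 0.927 to 0.991. The array of young_PPB replicate 3 lay apart on the third component, at 34.9, and had the lowest mean r with its own group, 0.967. A measure of RNA quality moved with age: the 3' to 5' difference of GAPDH was 0.31 ± 0.06 (SD, n = 6) in old dogs and 0.07 ± 0.09 in young dogs. The ages did not overlap (exact permutation p = 0.00216, the smallest that 924 splits can give; adjusted p = 0.0173 over 8 tests). The same measure for actin moved the other way, at 0.96 ± 0.17 (SD, n = 6) in old and 1.23 ± 0.24 in young dogs (exact permutation p = 0.0238, adjusted p = 0.0952). Between diets, the actin difference was 0.24 higher in PPB-fed dogs (exact permutation p = 0.0736, adjusted p = 0.147) and the GAPDH difference 0.05 higher (exact permutation p = 0.584, adjusted p = 0.6).

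The first comparison asked how the cortex of old dogs differed from that of young dogs. The largest rises among named genes were in QRICH1 (Entrez gene 476629; 2.34 ± 0.38, log2 difference ± SE, n = 6 dogs per age), the RNA helicase DDX39B (Entrez gene 474839; 2.30 ± 0.24) and ANP32A (Entrez gene 403534; 2.01 ± 0.40). Next came SLC43A3 (Entrez gene 483494; 1.99 ± 0.34), HLA-DRB1 (Entrez gene 474860; 1.97 ± 0.27), a class II molecule that presents antigens, and the glucocorticoid-induced kinase SGK1 (Entrez gene 403647; 1.95 ± 0.34). They were followed by the stress-induced nuclear protein NUPR1 (1.94 ± 0.28), the calcium-binding protein S100A1 (1.92 ± 0.23), the actin-binding calponin CNN3 (1.92 ± 0.22) and the splicing factor SRSF1 (1.88 ± 0.18). In old dogs HLA-DRB1 stood at 9.88 ± 0.46 (SD, n = 6) and in young dogs at 7.91 ± 0.61, or 3.91-fold lower. QRICH1, DDX39B, SLC43A3 and SGK1 had young means of 3.83, 3.82, 3.03 and 3.19, under the intensity minimum of 4, so their folds are uncertain and may be understated. The values of these 10 genes were above those of every young dog in 6 of 6 old dogs, except QRICH1 (5 of 6).

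Of the 10 largest falls, 9 are given here. They included those of the ubiquitin ligase RNF165 (Entrez gene 490468; -2.40 ± 0.25, n = 6 dogs per age) and the synaptotagmin-like gene SYT17 (Entrez gene 479829; -2.09 ± 0.42). Others were in MEDAG (Entrez gene 607966; -1.74 ± 0.21), neuropeptide Y, NPY (Entrez gene 475257; -1.68 ± 0.24), and the axon guidance receptor EPHA4 (Entrez gene 478925; -1.61 ± 0.16). TCAP, known as a muscle sarcomere protein, fell by 1.60 ± 0.18, and the substance P precursor TAC1 fell by 1.60 ± 0.13. The corticotropin-releasing hormone gene CRH fell by 1.52 ± 0.27, and the cadherin CDH6 fell by 1.47 ± 0.29. NPY stood at 9.63 ± 0.54 (SD, n = 6) in old dogs and 11.3 ± 0.27 in young dogs. The values of these 9 genes were below those of every young dog in 6 of 6 old dogs.

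In all, 2724 of 10835 probe sets (25.1%) differed between the ages in limma at an adjusted p under 0.05, 1214 higher and 1510 lower in old dogs. At least 2-fold differences were found in 390 of them, 233 higher and 157 lower. Centring each array on its median gave 1386 higher and 1296 lower, so which direction was more frequent depends on that step. The count was 1442 when a 1.5-fold change was also required, and 1322 over the 4527 genes. It was 1181 with globin-related probe sets as a covariate, 856 with the actin 3' to 5' difference as a covariate and 0 with that of GAPDH, which does not overlap between the ages. Of the 4527 genes, 11% rose and 15.9% fell when adjusted over all probe sets. The counts of list members below are to be read against these shares.

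**Figure D1:**
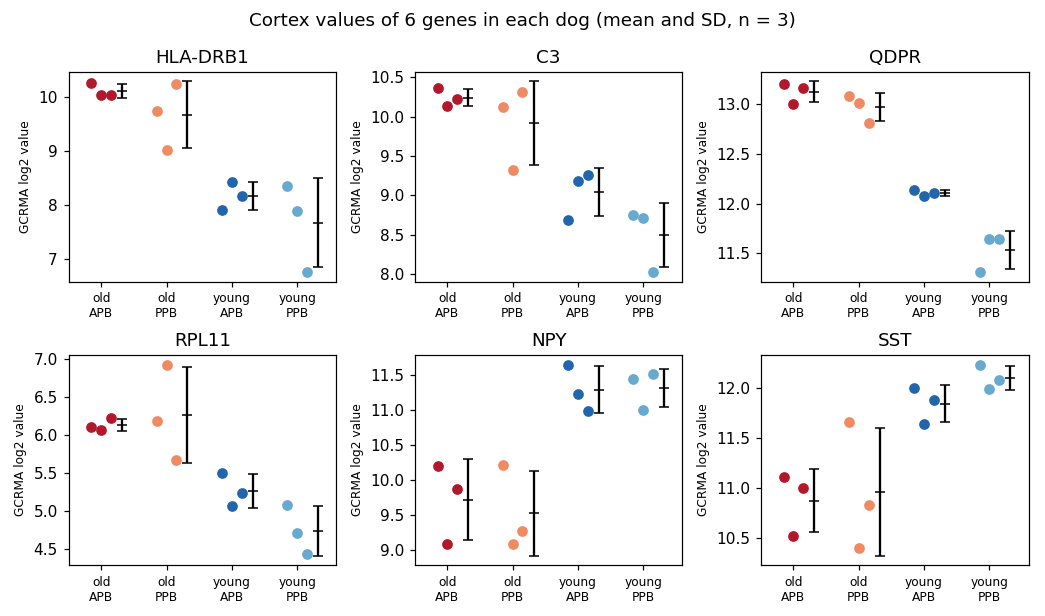
GCRMA log2 values of HLA-DRB1, C3, QDPR, RPL11, NPY and SST in each of the 12 dogs by group, with 1 point per dog and, beside the points, the mean and SD of the group (n = 3); the vertical axes do not start at 0. The old dogs lie above all young dogs for HLA-DRB1 (9.02 to 10.2 against 6.75 to 8.42), and below them for NPY (9.09 to 10.2 against 10.99 to 11.6).

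Markers of inhibitory interneurons were lower in old dogs. Of 7 measured members, 6 fell (6 adjusted over the list alone): NPY, TAC1, somatostatin (SST, -1.05 ± 0.19, n = 6 dogs per age), the neuropeptide cholecystokinin (CCK, -0.80 ± 0.11), reelin (RELN, -0.91) and the vesicular GABA transporter SLC32A1 (-0.60). The GABA-synthesizing enzyme GAD1 did not pass, at -0.01 ± 0.19. The list of appetite and metabolic neuropeptides shares NPY, CCK and SST with it and had 6 of 11 members fall (6 adjusted over the list alone). These included the enkephalin precursor PENK (-1.18 ± 0.14), CRH and the somatostatin receptor SSTR1 (-0.86 ± 0.13), while NPY1R had a difference of -0.04. The list medians were -0.91 and -0.80, and camera gave an adjusted p of 7.15e-04 for each. With an estimated correlation the adjusted p was 0.35 for the interneurons and 0.527 for the neuropeptides, and fry gave 1.1e-04 and 0.00189.

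Myelin genes were higher in old dogs. Of 8 measured members of the oligodendrocyte and myelin list, 6 rose (6 adjusted over the list alone). They included QDPR (Entrez gene 479082; 1.22 ± 0.09, n = 6 dogs per age), a pteridine reductase, and the small heat shock protein CRYAB (0.99 ± 0.16). Others were the lipid-forming enzyme ENPP2 (0.77 ± 0.13), the gap junction gene GJB1 (0.91 ± 0.20) and myelin basic protein, MBP (0.41). The members MAG, a myelin glycoprotein (0.27), and ENPP6 (-0.36) did not pass. The list median was 0.72 and camera gave an adjusted p of 4.44e-04, with adjusted p = 0.306 with an estimated correlation and 1.39e-04 by fry. The 3' to 5' difference of GAPDH, which was higher in old dogs by 0.24, moved with the age difference of this list and of each other list of the age comparison. The mean of the myelin list was 0.61 ± 0.08 (SE) higher in old dogs, and that of the neuron list differed by -0.12 ± 0.09. Whether the share of white matter in the samples differed between the ages was not tested.

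By camera at the preset correlation, the lists of complement and antigen presentation and of microglia and macrophage markers were also higher in old dogs. In the list of complement and antigen presentation, 12 of 19 members rose (13 adjusted over the list alone) and 1 fell. The risers included HLA-DRB1, the central complement component C3 (Entrez gene 476728; 1.31 ± 0.19, n = 6 dogs per age; 2.48-fold), the complement proteases C1R (1.01 ± 0.19) and C2 (0.88), and the immunoproteasome subunit PSMB8 (1.04), whereas the peptide transporter TAP2 fell by 0.96 ± 0.18. C3 had 6 probe sets, and the other 5 had the same sign. The class II genes DLA-DRA (1.61 ± 0.26) and DLA-DQB1 (1.76 ± 0.31) rose by their most intense probe set but did not pass by the mean of their probe sets (adjusted p = 0.219 and 0.0679). The list median was 0.81 and camera gave an adjusted p of 4.69e-06, with adjusted p = 0.55 with an estimated correlation and 0.0193 by fry. Of 10 microglia and macrophage markers, 3 rose (3 adjusted over the list alone), the lysosomal membrane protein LAPTM5 (1.37 ± 0.18), the signalling adaptor TYROBP (1.19 ± 0.20) and C1QA, which both lists hold, and lysozyme, LYZ, fell by 0.65 ± 0.16. C1QA did not pass without old_PPB replicate 1 (adjusted p = 0.0585), young_APB replicate 1 (0.0602), young_PPB replicate 1 (0.0531), young_APB replicate 3 (0.0613) or young_PPB replicate 3 (0.0505).

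The microglia list had a median of 0.36 and a camera adjusted p of 0.0323, with adjusted p = 0.792 with an estimated correlation and 0.0443 by fry. That call did not pass without old_PPB replicate 1 (adjusted p = 0.0632), old_PPB replicate 3 (0.0526) or young_PPB replicate 3 (0.0743), nor with arrays centred on their median (0.0521). Among 7 inflammatory and acute phase genes, the receptor TLR4 rose (0.80 ± 0.11, n = 6 dogs per age) and the inhibitor NFKBIA fell by 0.90 ± 0.17 (2 and 1 adjusted over the list alone; median 0.35, camera adjusted p = 0.163). Probe sets of LOC609402, which neighbours the globin gene HBE1, were 1.59 to 2.71 higher in old dogs (adjusted p = 0.171 to 0.0431) and moved with the complement and microglia lists.

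By camera at the preset correlation, the list of ribosomal protein genes was higher in old dogs and that of oxidative phosphorylation lower. Of 56 ribosomal protein genes, 21 rose and 0 fell (23 and 0 adjusted over the list alone). Rises included RPL11 (Entrez gene 100684296; 1.19 ± 0.20, n = 6 dogs per age), RPS25 (0.97 ± 0.17), RPS3A (0.88 ± 0.15) and RPL30 (0.53 ± 0.10). The list median was 0.25 and camera gave an adjusted p of 3.25e-08, with adjusted p = 0.495 with an estimated correlation and 0.00814 by fry. Of 43 respiratory chain genes, 14 fell and 0 rose (14 and 0 adjusted over the list alone). Falls included UQCRFS1 (-0.59 ± 0.12), COX5A (-0.48 ± 0.09), ATP5MC1 (-0.47 ± 0.09) and NDUFS4 (-0.41 ± 0.09), parts of complexes III, IV, V and I. The list median was -0.21 and camera gave an adjusted p of 0.0181, with adjusted p = 0.808 with an estimated correlation and 0.0193 by fry. This call did not pass without old_PPB replicate 3 (adjusted p = 0.0526) or young_PPB replicate 2 (0.0786).

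**Figure D2:**
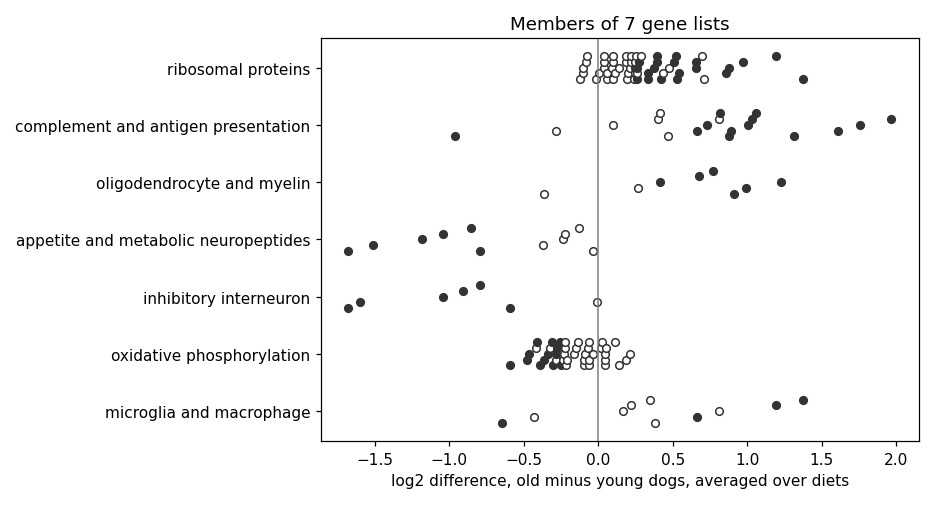
Log2 difference between old and young dogs (horizontal axis, averaged over diets, n = 6 dogs per age) of each measured member of the 7 gene lists that camera called for age; filled points passed the test over all probe sets and open points did not, and the vertical spread within a list only separates the points. No ribosomal protein gene that passed lies left of 0, and no oxidative phosphorylation gene that passed lies right of 0; the lowest complement and antigen presentation point is TAP2 at -0.96.

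Camera called none of the other 24 lists for age. Among 14 genes of growth factor signalling, 7 fell and 1 rose (9 and 2 adjusted over the list alone). Falls were seen in brain-derived neurotrophic factor, BDNF (-0.78 ± 0.13, n = 6 dogs per age), the neurotrophin receptor NTRK3 (-0.76 ± 0.12) and FGF13 (-0.53 ± 0.09), and a rise in FGF1 (0.41). Its median was -0.38 (camera adjusted p = 0.0893; fry 5e-06). Of 12 genes of neural development, 5 fell and 3 rose (5 and 3 adjusted over the list alone). EPHA4 and the growth cone protein GAP43 (-0.88 ± 0.12) fell and tau, MAPT, rose (0.68 ± 0.10; median -0.22, camera adjusted p = 0.709, fry 0.0315). Of 20 extracellular matrix genes, 5 fell (7 adjusted over the list alone), among them FBLN2 (-0.88 ± 0.20) and the basement membrane collagens COL4A1 (-0.66 ± 0.16) and COL4A2 (-0.46 ± 0.11; median -0.30, camera adjusted p = 0.11, fry 0.0337). Of 16 calcium genes, 4 rose and 1 fell (6 and 2 adjusted over the list alone). Rises were seen in the calcineurin subunit PPP3R1 (1.43 ± 0.16) and calmodulin, CALM3 (0.61 ± 0.11; median 0.00, camera adjusted p = 0.313, fry 0.0256). The calcium pump ATP2B2 (1.06 ± 0.09) had another probe set that passed in the opposite direction, and did not pass by their mean (adjusted p = 0.837).

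Camera called no list of the other cell types measured. Of 10 neuronal markers, 3 fell and 1 rose (4 and 1 adjusted over the list alone), with a fall of the glutamate transporter SLC17A7 (-0.79 ± 0.15, n = 6 dogs per age; list median -0.17, camera adjusted p = 0.709). Of 11 astrocyte markers, 2 rose and 1 fell (2 and 1 adjusted over the list alone), the latter the glutamate transporter SLC1A2 (-0.91 ± 0.14). The median was just below 0, the mean 0.07, and camera (up, adjusted p = 0.709) and fry (down) pointed opposite ways. In the endothelial list only VWF of 10 passed, and not without 9 of the 12 dogs in turn (0 adjusted over the list alone; median 0.02, camera adjusted p = 0.709). In the meningeal list 0 of 7 passed by limma (0 adjusted over the list alone), 2 of them, COL1A1 (-0.29) and PTGDS (0.33), with an unadjusted p of 0.0154 and 0.0157. The median was -0.19 and camera pointed up (adjusted p = 0.995). Of 10 synaptic vesicle genes, 4 fell and 1 rose (4 and 1 adjusted over the list alone), with a fall of SYT5 (-0.54 ± 0.13) and a rise of NAPB (0.45 ± 0.11; median -0.05, camera adjusted p = 0.805). Of 8 immediate early genes, only IER2 passed, and not without 8 of the 12 dogs in turn (0 adjusted over the list alone; median -0.23, camera adjusted p = 0.709).

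Among metabolic lists, 3 of 12 citric acid cycle genes fell and 1 rose (4 and 2 adjusted over the list alone). IDH1 rose (0.95 ± 0.16, n = 6 dogs per age) and MDH1 fell (-0.31 ± 0.07; median -0.19, camera adjusted p = 0.709, fry 0.0443). In glycolysis, 4 of 22 rose and 2 fell (4 and 2 adjusted over the list alone), with a rise of PFKM (0.43 ± 0.10) and a fall of LDHA (-0.52 ± 0.14; median 0.12, camera adjusted p = 0.432). Of 24 fatty acid genes, 2 rose and 2 fell (1 and 2 adjusted over the list alone), the falls in the desaturase FADS1 (-1.10 ± 0.15) and the binding protein FABP3 (-0.78 ± 0.15). Median and mean were -0.04 and -0.08, whereas camera pointed up (adjusted p = 0.902). Of 14 cholesterol genes, 4 rose and 3 fell (4 and 3 adjusted over the list alone), with a rise of STARD4 (0.50 ± 0.10) and a fall of the cholesterol hydroxylase CYP46A1 (-0.78 ± 0.14). Median and mean were -0.03 and -0.01 and camera pointed up (adjusted p = 0.825). In the insulin list 2 of 15 rose and 3 fell (2 and 3 adjusted over the list alone), with a rise of the deacetylase SIRT1 (0.94 ± 0.20; median -0.08, camera adjusted p = 0.902). In the list of thyroid hormone, vitamin and retinoid signalling, 2 of 8 fell and 1 rose (3 and 1 adjusted over the list alone), with a fall of the thyroid receptor THRA (-0.84 ± 0.16; median -0.21, camera adjusted p = 0.709). Of 15 glucocorticoid-responsive genes, 4 fell and 2 rose (4 and 3 adjusted over the list alone), with a rise of SGK1 and a fall of NR3C2 (-0.53 ± 0.10). The median was 0.11 (camera adjusted p = 0.709) and fry pointed down.

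Camera called no list of protein care or cell damage either. Of 21 heat shock and chaperone genes, 5 fell and 2 rose (6 and 3 adjusted over the list alone), with a fall of HSPD1 (-0.38 ± 0.09, n = 6 dogs per age; median 0.07, camera adjusted p = 0.709). The measured members do not include the heat shock gene HSP70, whose probe sets rose by 1.47 ± 0.13 and 1.40 ± 0.15 (limma adjusted p = 0.000273 and 0.000377). Of 23 antioxidant genes, 6 fell and 4 rose (6 and 4 adjusted over the list alone), with a fall of GSTA4 (-0.57 ± 0.08) and a rise of GPX3 (0.73 ± 0.14). The median was -0.07 and camera pointed up (adjusted p = 0.943). Of 32 proteasome genes, 5 fell and 3 rose (5 and 3 adjusted over the list alone), with a fall of PSMA7 (-0.70 ± 0.11) and a rise of PSMD11 (0.68 ± 0.11; median -0.11, camera adjusted p = 0.709). Of 27 lysosome and autophagy genes, 4 rose and 3 fell (4 and 3 adjusted over the list alone), with a rise of the cholesterol-binding NPC2 (1.04 ± 0.13; median 0.01, camera adjusted p = 0.709). Of 19 genes of amyloid, tau and neurodegeneration, 4 rose and 1 fell (4 and 1 adjusted over the list alone), with rises of MAPT, APLP2 (0.85 ± 0.14) and the lipocalin APOD (1.39 ± 0.33; median 0.09, camera adjusted p = 0.455). Of 10 DNA damage genes, only the cell cycle inhibitor CDKN1A passed, and it fell by 1.15 ± 0.27 (1 adjusted over the list alone). The median was 0.03, the mean -0.09 and camera pointed up (adjusted p = 0.805).

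Some list members counted above as past the threshold for age did not pass in every fit. Of the 12 fits that each left out 1 dog, NEFM (neuronal, -0.57), PIK3R1 (insulin, -0.39) and CRABP1 (retinoid, -0.79) did not pass in 10, and DLD (citric acid cycle, -0.43) and ECHS1 (fatty acid, 0.38) in 9. The 2 astrocyte risers, ALDOC (0.46; also in glycolysis) and GLUL (0.36), did not pass in 8, TSC2 (insulin, -0.31) in 7, GSK3B (insulin and amyloid, -0.55) in 3, DNM1 (synaptic vesicle, -0.32) in 2, and LAMB1 (extracellular matrix, -0.44) and HADHA (fatty acid, 0.32) in 1. By the mean of all probe sets of a gene, MAP2 (neuronal, 0.68; adjusted p = 0.468), STMN2 (neuronal and neural development, -0.44; 0.0634), HSPH1 (-0.46; 0.303) and CCT3 (0.52; 0.209) of the chaperones did not pass. The same held for PDK1 (glycolysis, 0.78; 0.0813), HMGCS1 (cholesterol, -0.74; 0.577), SLC23A2 (vitamin, 0.61; 0.246), GSK3B (0.0858) and PIK3R1 (0.15). Under quantile normalization DLD (0.0503), TSC2 (0.0653) and CRABP1 (0.0554) did not pass.

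The age difference was also taken within each diet. In APB-fed dogs QDPR rose by 1.01 and in PPB-fed dogs by 1.44, and TAC1 changed by -1.64 and -1.56 (n = 3 dogs per group). In APB-fed dogs 755 probe sets passed in limma, 366 higher and 389 lower in old dogs, and in PPB-fed dogs 758, 320 higher and 438 lower. Of these, 209 were higher in both diets and 241 were lower in both. Independent lists would share 10.8 higher probe sets. These lists are not independent, since both contrasts use the same estimate of spread for each probe set. Passing in opposite directions was found for 0. Of the 1063 probe sets that passed in either diet, 1058 (99.5%) had the same sign in the other. Across all 10835 probe sets, which are not independent replicates, the age differences in APB-fed and PPB-fed dogs had a Pearson's r of 0.83, with the same sign in 81.3%. For PPB-fed dogs, a fit on the 6 arrays of that diet alone called 0 probe sets (2253 at an unadjusted p under 0.05; smallest adjusted p = 0.0533), against 634 in the same fit for APB-fed dogs.

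Single dogs moved these within-diet counts by more than 1.5 times. For APB-fed dogs the count was 313 without old_APB replicate 1, 195 without old_APB replicate 2, 212 without young_APB replicate 1, 337 without young_APB replicate 2, 199 without young_APB replicate 3 and 1197 without young_PPB replicate 3, which enters through the shared spread. For PPB-fed dogs it was 315 without old_PPB replicate 2, 127 without old_PPB replicate 3 and 346 without young_PPB replicate 2.

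The next comparison asked how the cortex differed between diets. No gene passed over all probe sets. The named genes with the smallest p were lower in PPB-fed dogs. They were the receptor TLR4 (Entrez gene 403417; -0.59 ± 0.11, n = 6 dogs per diet), PDLIM1 (-0.52 ± 0.10), SHISAL2A (-0.44 ± 0.09), FEZ1 (-0.39 ± 0.09) and the peptidase BLMH (-0.38 ± 0.08). Beside these stood GJB1 (Entrez gene 480953; -0.90 ± 0.20), the steroid reductase SRD5A1 (-0.53 ± 0.12), progranulin, GRN (-0.52 ± 0.12), SMYD2 (-0.57 ± 0.13) and DBNDD2 (-0.43 ± 0.10). Each had an adjusted p of 0.403. TLR4 stood at 5.29 ± 0.58 (SD, n = 6) with APB and 4.70 ± 0.37 with PPB. In limma, 0 of 10835 probe sets passed, with 1030 at an unadjusted p under 0.05 (398 higher and 632 lower with PPB; 542 expected by chance) and a smallest adjusted p of 0.394. With no intensity filter, or without moderation, 1 unnamed probe set passed (-0.21). Without old_APB replicate 3, GJB1 (-1.10, adjusted p = 0.0355) and 1 unnamed probe set passed.

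Myelin genes had lower values with PPB. All 8 measured members of the oligodendrocyte and myelin list were lower, by a median of -0.52. None passed over all probe sets, and 6 fell when adjusted over the list alone: GJB1, MAG (-0.58 ± 0.14, n = 6 dogs per diet), ENPP2 (-0.53 ± 0.13), QDPR (-0.37 ± 0.09), CRYAB (-0.56 ± 0.16) and MAL (-0.51). Camera gave an adjusted p of 8.41e-06, with adjusted p = 0.089 with an estimated correlation and 0.00592 by fry. The mean of the list was -0.49 ± 0.08 (SE). Beside it, the actin 3' to 5' difference was 0.24 higher in PPB-fed dogs, and the mean of the neuron list differed by -0.05 ± 0.09.

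**Figure D3:**
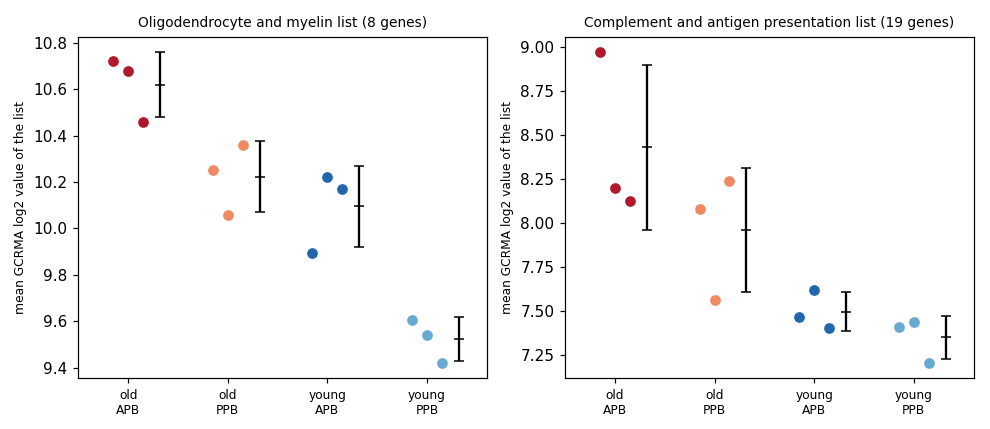
Mean GCRMA log2 value of the 8 oligodendrocyte and myelin genes (left) and of the 19 complement and antigen presentation genes (right) in each of the 12 dogs by group, with 1 point per dog and the mean and SD of the group (n = 3) beside the points; the vertical axes do not start at 0. The myelin mean is 0.61 higher in old than in young dogs and differs by -0.49 with PPB, and the complement mean is 0.77 higher in old than in young dogs.

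Camera called 7 more lists for diet, in none of which a member passed over all probe sets in limma. The median diet difference over all 4527 genes was -0.05, so counts of lower members are to be read against a background below 0. None of the 8 calls held with an estimated correlation, where the adjusted p was 0.404 for antioxidant and glucocorticoid-responsive genes and 0.582 for the other 5 lists beside myelin. Complement and antigen presentation was lower with PPB (median -0.31, adjusted p = 0.0136; 17 of 19 members lower, 0 adjusted over the list alone). C1QA was at -0.62 ± 0.19 and the immunoproteasome subunit PSMB9 at -0.50 ± 0.16 (n = 6 dogs per diet). Antioxidant defence was lower (median -0.18, adjusted p = 0.0136; 20 of 23 members lower, 0 adjusted over the list alone), with GPX3 at -0.44 ± 0.14. So were oxidative phosphorylation (median -0.12, 0.0242; 36 of 43 lower, 0 adjusted over the list alone) and glucocorticoid-responsive genes (median -0.22, 0.0242; 14 of 15 lower, 0 adjusted over the list alone), with the cortisol-forming enzyme HSD11B1 at -0.84 ± 0.29. Lysosome and autophagy was lower (median -0.13, 0.0268; 23 of 27 lower), and GRN fell when adjusted over the list alone. In the inflammatory list TLR4 did so (median -0.37, 0.0319; 6 of 7 lower). Extracellular matrix was higher (median 0.14, 0.0136; 14 of 20 higher), with COL1A1 (0.42 ± 0.10) past the threshold adjusted over the list alone and TIMP1 at -0.47 ± 0.23.

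By fry, antioxidant and glucocorticoid-responsive genes had an adjusted p of 0.0442 each, and the other 5 had 0.0727 to 0.281. Leaving out young_PPB replicate 3 ended the calls of complement (adjusted p = 0.0673), inflammatory (0.147), oxidative phosphorylation (0.0734), extracellular matrix (0.0553) and glucocorticoid-responsive genes (0.0673). Leaving out old_APB replicate 1 ended those of complement (0.0562), inflammatory (0.0569), lysosome (0.0787) and glucocorticoid-responsive genes (0.0562). Calls also ended without old_PPB replicate 1 (inflammatory, 0.0696; glucocorticoid, 0.0734), old_PPB replicate 2 (complement, 0.113; lysosome, 0.0935), old_PPB replicate 3 (oxidative phosphorylation, 0.0727), young_PPB replicate 1 (oxidative phosphorylation, 0.0573; lysosome, 0.0636), young_APB replicate 2 (extracellular matrix, 0.0503) and young_APB replicate 3 (inflammatory, 0.0614). The myelin and antioxidant calls passed without each dog in turn. Quantile normalization ended the calls of oxidative phosphorylation and lysosome (adjusted p = 0.0518 each). With no intensity filter the inflammatory call ended (0.407, median -0.01), and the extracellular matrix call stayed at 0.0315 with a median of 0.02.

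In the 23 lists that camera did not call for diet, 0 members passed over all probe sets in limma. Ribosomal protein genes had a median of -0.11 (48 of 56 lower; adjusted p = 0.0614), and glycolysis -0.18 (19 of 22 lower; 0.0591). The median was -0.40 for microglia and macrophage markers (8 of 10 lower; 0.0591), -0.12 for the proteasome (24 of 32 lower; 0.118) and 0.14 for appetite neuropeptides (8 of 11 higher; 0.0591). Adjusted over the list alone, 2 of 10 microglia markers fell, LAPTM5 (-0.63 ± 0.18, n = 6 dogs per diet) and C1QA, and LYZ rose (0.54 ± 0.16). On the same basis 2 of 11 astrocyte markers fell, ALDH1L1 (-0.61 ± 0.17) and S100B (-0.34 ± 0.10; list median -0.15, adjusted p = 0.427). BDNF rose in the growth factor list (0.57 ± 0.13; median 0.07, 0.0709), COL1A1 in the meningeal list (median 0.19, 0.146), and 2 of 12 neural development genes rose and 2 fell (median 0.03, 0.136), among them MARCKSL1 (-0.63 ± 0.17).

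No member passed, also when adjusted over the list alone, in the remaining lists. Their medians for diet were -0.06 in neurons, with camera pointing up (adjusted p = 0.738), 0.06 in inhibitory interneurons (0.427), -0.01 in endothelial cells, with a mean of 0.05 (0.427). They were 0.17 in immediate early genes (0.0609), 0.05 in calcium genes (0.0744), -0.12 in heat shock genes (0.741), -0.11 in synaptic vesicle genes (0.471) and -0.09 in the citric acid cycle (0.653). In fatty acid genes the median was -0.13, with an adjusted p of 0.181, and the others were -0.10 in amyloid and tau genes (0.359), -0.08 in cholesterol genes (0.579), -0.08 in DNA damage genes (0.579), -0.05 in insulin genes (0.801) and -0.01 in thyroid hormone, vitamin and retinoid genes, with camera pointing up (0.801).

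Within each age, no gene passed for diet. Among named genes, the smallest p in old dogs were those of TLR4 (-0.83 ± 0.16, log2 ± SE, PPB minus APB, n = 3 dogs per group), VPS35L (-0.64 ± 0.14), PSMB9 (-0.92 ± 0.22), MCAT (-0.53 ± 0.14) and SQOR (-0.85 ± 0.22). Each had an adjusted p of 0.921. In young dogs they were those of KCNIP2 (-0.63 ± 0.12), COL1A1 (0.74 ± 0.14), BDNF (0.88 ± 0.19), PDLIM1 (-0.65 ± 0.14) and QDPR (-0.58 ± 0.13), each with an adjusted p of 0.899, and 1 unnamed probe set had a smaller one, 0.197. In limma 0 of 10835 probe sets passed in old dogs, with 502 at an unadjusted p under 0.05, and 0 in young dogs, with 538, where 542 are expected by chance. Without moderation 1 unnamed probe set passed in old dogs (-0.39), and 0 in young dogs. Across probe sets, the diet differences in old and young dogs had a Pearson's r of 0.44, with the same sign in 68%, and r was 0.212 with the GAPDH difference as a covariate and 0.279 without old_APB replicate 1.

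The last comparison asked whether the diet difference depended on age. The named genes with the smallest p were the DNA repair gene DDB1, at 0.22 in old and -0.37 in young dogs (interaction 0.60 ± 0.18, n = 3 dogs per group), and the potassium channel partner KCNIP2 (interaction 0.53 ± 0.17). They were followed by COL1A1 (-0.62 ± 0.20), AIFM2 (0.86 ± 0.29) and the Notch pathway factor RBPJ (-0.90 ± 0.32). Each had an adjusted p of 1. In limma 0 of 10835 probe sets passed, with 125 at an unadjusted p under 0.05, fewer than the 542 expected by chance. Without moderation, 1 unnamed probe set passed (-0.37).

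Camera called 4 lists for the interaction, in which 0 members passed in limma, also when adjusted over the list alone. With an estimated correlation the adjusted p was 0.969 for each, and by fry 0.976. Complement and antigen presentation had a median diet difference of -0.49 in old and -0.12 in young dogs (median interaction -0.38, adjusted p = 0.00237). PSMB9 was at -0.92 in old and -0.07 in young dogs (interaction -0.85 ± 0.32, n = 3 dogs per group). Extracellular matrix had 0.03 in old and 0.20 in young dogs (interaction -0.20, adjusted p = 0.00994), oxidative phosphorylation -0.09 and -0.16 (0.10, 0.0425), and ribosomal proteins -0.06 and -0.15 (0.11, 0.0425). Each of these calls ended without at least 1 of the dogs, and that of ribosomal proteins also turned its direction without young_PPB replicate 3 (median -0.02, adjusted p = 0.852). The calls of oxidative phosphorylation and ribosomal proteins also ended under quantile normalization (adjusted p = 0.0569 and 0.067), with arrays centred on their median (0.061 and 0.0703) and by the mean of all probe sets of a gene (0.055 and 0.147), and that of ribosomal proteins with no intensity filter (0.0713). Replicate numbers as blocks over all groups also ended the call of ribosomal proteins. For complement the median interaction was -0.02 without old_APB replicate 1 (adjusted p = 0.541), -0.21 without old_PPB replicate 2 (0.694) and -0.29 without young_PPB replicate 1 (0.0848). For extracellular matrix it was -0.08 without old_PPB replicate 2 (0.323), -0.19 without old_APB replicate 3 (0.0531), -0.07 without young_APB replicate 2 (0.288) and -0.07 without young_PPB replicate 3 (0.193).

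The 27 lists that camera did not call for the interaction had adjusted p-values from 0.0818 (meninges and fibroblast, median -0.16) and 0.0843 (microglia and macrophage, median -0.18) to 0.976, and 0 members passed in them. Oligodendrocyte and myelin genes had a median interaction of 0.16 (adjusted p = 0.106). Median, mean and test differed in sign for the endothelial list (median 0.11, mean 0.01, camera down) and for the thyroid hormone, vitamin and retinoid list (median -0.01, mean 0.10, camera down). They also differed for the glucocorticoid-responsive list (median 0.01, mean -0.04, camera down, fry up) and for DNA damage genes (median 0.07, mean -0.04, camera up).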

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

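In this part, the splits at an unadjusted p were chosen after the result was seen. The results below were singled out because the diet difference of a gene list differed between the ages by a test of that difference itself, the age by diet interaction in camera at the preset correlation. None of the 4 calls held with a correlation estimated for each list (adjusted p = 0.969 each) or by fry (0.976 each). With 3 dogs in each group, no test for a single outlying dog applied.

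Complement and antigen presentation genes had a median diet difference (PPB minus APB, n = 3 dogs per group) of -0.49 in old and -0.12 in young dogs, a median interaction of -0.38 with an adjusted p of 0.00237. Extracellular matrix and collagen genes had 0.03 in old and 0.20 in young dogs, a median interaction of -0.195 (adjusted p = 0.00994). Oxidative phosphorylation genes had -0.09 and -0.16, a median interaction of 0.104 (adjusted p = 0.0425), and ribosomal protein genes -0.06 and -0.15, a median interaction of 0.111 (adjusted p = 0.0425).

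Single dogs carried much of these differences. Without old_APB replicate 1 the median interaction of complement genes was -0.02 (adjusted p = 0.541), and without old_PPB replicate 2 it was -0.21 (0.694). That of extracellular matrix genes was -0.08 without old_PPB replicate 2 (0.323), -0.07 without young_APB replicate 2 (0.288) and -0.07 without young_PPB replicate 3 (0.193). Without young_PPB replicate 3 the median was 0.04 in oxidative phosphorylation genes (0.552) and -0.02 in ribosomal protein genes (0.852), and leaving out 8 of the 12 dogs in turn ended the call of each of these 2 lists. Both calls also ended under quantile normalization (adjusted p = 0.0569 and 0.067) and by the mean of all probe sets of a gene (0.055 and 0.147). Replicate numbers as blocks over all groups also ended the call of ribosomal proteins.

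Chance was not excluded for these 4 calls. When diet labels were permuted within each age, 48 of 100 splits, the real one included, gave at least as many interaction calls, where the real split gave 4 and the highest of the others 13. The other splits had a median of 3 calls, so the preset correlation of 0.01 calls lists in regrouped dogs of these data as well. For single genes limma called 0 probe sets for the interaction (125 at an unadjusted p under 0.05; 1 without moderation). A count of 0 is reached in 100 of 100 splits whatever the data (highest of the others 3), so that comparison says nothing of chance. At an unadjusted p under 0.05 chance was not excluded, with 99 of 100 splits at 125 or more and 2224 as the highest of the others. No technical or biological explanation was weighed for these 4 lists, since regrouped dogs gave as many calls.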

How the results depend on the processing

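The actin, GAPDH and globin covariate fits of the counts and agreements, and median centring for the gene lists, were chosen after the result was seen. The age count stayed within 1.5 times of 2724 under quantile normalization (2700), centring on the median (2682), a variance trend (2783), robust moderation (2649), array weights (3759), no moderation (2154), a filter at log2 6 (2504), no intensity filter (1828) and without each dog in turn (1873 to 2710). Where no cause is given below, the cause was not tested.

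With no intensity filter, 23836 probe sets were tested, and the counts were 325 for age in APB-fed and 383 in PPB-fed dogs, 1 for diet, 1 for diet in old dogs and 1 for the interaction, with an r of 0.805 between the age differences of the diets. The filter at log2 6 gave an r of 0.857. Array weights, whose estimation stopped before it converged, gave 1765 and 1612 for age in APB-fed and PPB-fed dogs. With no moderation the counts were 431 and 496, with 1 for diet, 1 for diet in old dogs and 1 for the interaction. A stricter threshold, at least 1.5-fold, gave 1442 for age, and a looser adjusted p under 0.10 gave 1419 and 1496 within APB and PPB. Over 4527 genes with 1 probe set per gene, fewer tests gave 1322 for age, 371 in APB-fed and 394 in PPB-fed dogs. With only the 2 groups compared in the fit, limma called 634 for age in APB-fed dogs and 0 in PPB-fed dogs (2253 at an unadjusted p under 0.05). Fewer dogs set the spread in both of these fits, so that alone does not account for the 0.

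With the actin covariate the age counts were 856, 322 in APB-fed and 85 in PPB-fed dogs, and with the globin covariate 1181, 436 and 67, with an r of 0.353 between the diet differences of the ages. With the GAPDH covariate, which does not overlap between the ages and raised the median SE of the age calls from 0.139 to 0.297, limma called 0, 0 and 2, with an r of 0.878 for age and 0.212 for diet.

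Camera with an estimated correlation called 0 lists for age, 0 for diet and 0 for the interaction, and fry 12, 3 and 0. For the interaction 2 lists were called under quantile normalization, 2 with arrays centred on their median and 2 with the mean of all probe sets of a gene; the lists lost in each were oxidative phosphorylation and ribosomal proteins.

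Leaving out each dog in turn gave 195 (without old_APB replicate 2) to 1197 (without young_PPB replicate 3) for age in APB-fed dogs, and 127 (without old_PPB replicate 3) to 762 (without old_APB replicate 1) in PPB-fed dogs. The remaining groups of 2 dogs take their spread from all groups. The count for diet was 0 to 2 (without old_APB replicate 3). The agreement across strata was 0.777 to 0.827 for age and 0.279 (without old_APB replicate 1) to 0.5 for diet. Lists called were 5 to 8 for age, 4 (without young_PPB replicate 3; 5 without old_APB replicate 1) to 13 (without young_APB replicate 1) for diet, and 1 (without old_APB replicate 3 or young_APB replicate 2) to 5 (without old_PPB replicate 3) for the interaction, with 2 without old_APB replicate 1, old_PPB replicate 2, young_PPB replicate 1 or young_PPB replicate 3. The ribosomal protein interaction had an adjusted p of 0.000973 (without young_PPB replicate 2) to 0.852 (without young_PPB replicate 3, where its median turned to -0.0212).

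Replicate numbers were not shown to pair the dogs: 11 of 18 same-numbered pairs had an r over 0.1, from -0.374 to 0.512, with a mean of 0.146 against -0.0714 for other numbers. Between the diets all 3 such pairs of old dogs (0.512, 0.31 and 0.165) and 1 of 3 of young dogs (0.387) exceeded 0.1, and not every dog correlated best with its own number. With the numbers as blocks, the counts were 3108 for age, 980 and 977 within the diets, and 0 for diet and the interaction. Blocks within each age gave 911 probe sets for diet in old dogs at an unadjusted p under 0.05, against 502 with no block. On the same basis there were 805 against 538 for diet in young dogs, 1595 against 1030 for diet and 203 against 125 for the interaction. Blocks over all groups ended the ribosomal protein interaction call (adjusted p = 0.0527). Of 112 named genes past the threshold for age, 26 were lost in at least 1 setting where single genes were followed. These settings were quantile normalization, replicate numbers as blocks, the mean of all probe sets of a gene, and leaving out each dog in turn. The covariate fits were not among them, and with the GAPDH covariate limma called 0 probe sets for age. GCRMA values give no detection calls, so signal near the background makes folds of low genes uncertain, and they may be understated.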

Other observations

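Chosen after the result was seen were the splits at an unadjusted p, the degraded RNA test and the actin and GAPDH covariate tests of the age count, the neuron list test of white matter, and the splits that let any list stand out. The covariates were added after the data were seen, but the covariate tests of the 2 list means were fixed before their own result. In all splits the labels were permuted, 100 splits were drawn where more exist, and the counts include the real one.

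For age, limma called 2724 probe sets, and chance was excluded, since 1 of 100 splits gave as many and the highest of the others gave 5. Degraded RNA in the old dogs' samples cannot be told apart from age, since the actin 3' to 5' difference was -0.273 in old minus young dogs (exact permutation p = 0.0238; -0.183 and exact permutation p = 0.0563 without young_PPB replicate 3) while that of GAPDH was higher. RNA quality as the actin difference measures it is argued against as the whole cause. With that covariate the 2724 probe sets kept a median share of 0.863 of their age difference, and 751 of them still passed. Their median size was 0.603 before and 0.528 after, and their median SE was 0.139 before and 0.18 after. It does not settle the point, since a covariate measured with error removes only a part of an effect. These probe sets were also chosen for passing the age test, and actin and GAPDH moved opposite ways with age. With the GAPDH covariate the median share was 1.04 but 0 passed, the median SE being 0.297, so RNA quality as GAPDH measures it cannot be told apart from age, because the ages do not overlap in it. Age, feeding regimen, array order and the share of white matter in the samples stay open as untested, and RNA quality stays open as well.

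The oligodendrocyte and myelin list mean was lower in PPB-fed dogs (-0.485 ± 0.0831, SE, n = 6 dogs per diet), and chance was excluded for this list alone, with 1 of 100 splits as large and 0.452 as the highest of the others. When any of the 31 lists could stand out, chance was not excluded: 19 of 100 splits gave a camera p as small (real 2.71e-07, smallest of the others 5.65e-10). RNA quality as the actin difference measures it is argued against as the whole cause, since with it the list mean was -0.395 ± 0.106. It does not settle the point, since a covariate measured with error removes only a part of an effect. Across all dogs, old_APB replicates 1 and 2 had the lowest actin differences (0.767 and 0.75) and the highest myelin means (10.72 and 10.68). The array of young_PPB replicate 3 had the highest actin difference (1.68) and the lowest myelin mean (9.42). The GAPDH difference was not used as a covariate for the myelin list. A smaller share of white matter in the samples cannot be told apart from a diet difference, since the neuron list mean, at -0.0466 ± 0.0861, lay within its error of 0. RNA quality therefore stays open, as does diet, which was not tested.

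The complement and antigen presentation list mean was higher in old dogs (0.772 ± 0.176, SE, n = 6 dogs per age), and chance was excluded for this list alone, with 1 of 100 splits as large and 0.73 as the highest of the others. When any list could stand out, chance was not excluded: 32 of 100 splits gave a camera p as small (real 3.03e-07, smallest of the others 1.44e-12). With the globin-related probe sets as a covariate for blood left in the samples, the list mean was 0.535 ± 0.206. With the actin difference it was 0.579 ± 0.242. This argues against blood or RNA quality, as these covariates measure them, as the whole cause. It does not settle the point, since a covariate measured with error removes only a part of an effect. The GAPDH difference, which does not overlap between the ages, was not used as a covariate for this list. Blood and RNA quality therefore stay open, as does age, which was not tested.

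Chance was not excluded for the counts of lists called by camera: 8 of 100 splits gave as many for age (real 7, highest of the others 10) and 9 of 100 for diet (real 8, highest 13). For diet limma called 0 probe sets (1 without moderation), a count that 100 of 100 splits reach whatever the data (highest of the others 2), so it says nothing of chance. At an unadjusted p under 0.05 there were 1030, and chance was not excluded, with 11 of 100 splits as large and 2631 as the highest of the others. It was excluded for the agreement of the age effect between diets (r = 0.83, 1 of 100 splits, highest of the others 0.641). For the agreement of the diet effect between ages (r = 0.44), the share was under 0.05 with all dogs (3 of 100 splits, highest of the others 0.49). That r was 0.279 without old_APB replicate 1 and 0.212 with the GAPDH covariate, values not put through splits of their own. The agreement thus rests in part on 1 dog, and chance is not firmly excluded for it. Within a diet or an age, 10 splits are too few for a share under 0.05. The count for age was 755 in APB-fed dogs (1 of 10 splits, highest of the others 1) and 758 in PPB-fed dogs (1 of 10, highest 0), and that for diet was 0 in old dogs (highest of the others 1) and 0 in young dogs (highest 3), counts that 10 of 10 splits reach whatever the data.

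Some values were picked after they were seen. The heat shock gene HSP70 has 2 probe sets, and both rose in old dogs, by 1.47 ± 0.13 and 1.40 ± 0.15 (adjusted p = 0.000273 and 0.000377). For TTR, a carrier of thyroxine, the most intense probe set had an age difference of -0.21 ± 0.15 (adjusted p = 0.336), whereas the other 3 had -1.65 ± 0.40, -1.40 ± 0.38 and -1.30 ± 0.35 (adjusted p = 0.014, 0.0215 and 0.0216). Those 3 were higher with PPB, by 1.70, 1.27 and 1.28 (adjusted p = 0.403, 0.463 and 0.444). Of 1228 genes with several probe sets tested, 195 had at least 2 called for age, and 15 of these had calls in both directions, among them ATP2B1, ATP2B2 and MAP1B.

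Of the lists too small to test, 8 measured members passed for age in limma and 0 for diet or the interaction. NRXN3 (-0.68 ± 0.13, n = 6 dogs per age), GPHN (-0.82 ± 0.11), SLC32A1 and MCM7 (-0.63 ± 0.17) fell, and BHLHE41 (0.62 ± 0.10), NR1D2 (0.41 ± 0.11), HSD17B4 (0.30 ± 0.10) and ENPP2 rose. For age the medians were -0.41 in the glutamate receptor list (1 of 2 fell), -0.40 in the GABA list (2 of 4 fell), -0.26 in the cell cycle list (1 of 4 fell) and 0.07 in the circadian clock (2 of 4 rose). They were 0.10 in the isoflavone and oestrogen list (1 of 4 rose) and 0.76 in the interferon list, where 0 of 3 passed, with ISG15 at 1.95 ± 0.73 (adjusted p = 0.0706). Adjusted over their list alone, ISG15 and IRF9 (0.76 ± 0.28; 0.0319 each) also rose, and TYMS (-0.36 ± 0.13; 0.0315) and ARNTL (-0.35 ± 0.12; 0.0182) also fell. The choroid plexus list held only ENPP2, also a myelin member, and TTR, whose probe sets differ as given above, so its medians of 0.28 for age and -0.24 for diet, from the most intense probe set of TTR, go against the direction of the other 3. For diet the medians were 0.23 in glutamate receptors, -0.23 in GABA genes, -0.06 in cell cycle genes, 0.09 in clock genes, -0.14 in isoflavone and oestrogen genes and -0.50 in interferon genes. Adjusted over their list alone, HSD17B10 (-0.36 ± 0.10, adjusted p = 0.0149) and ENPP2 (-0.53 ± 0.13, 0.00297) were lower with PPB.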
